A study of Drosophila melanogaster with 2 samples.

How the data were processed

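The series holds 2 chromatin immunoprecipitation sequencing libraries from whole Drosophila melanogaster pupae of 48 h, males and females pooled, from a transgenic line in which GFP is fused to the C terminus of CG8301. Per the labels, the 2 libraries are biological replicates of 1 group, chromatin was sonicated to 200 to 800 bp, and a separate control experiment is listed. The labels disagree with each other on what the libraries are: the antibody field names CG8301 and the assay is given as transcription factor ChIP-seq, while the description text of both libraries calls them an input control. The lists do not settle this, so every region below is a region of these libraries and not necessarily a binding site of the fused protein.

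Region lists on assembly dm6 were used. The authors deposited 1 list of 30000 regions for each replicate and 1 of 30000 regions for the pooled replicates, each described as peaks and background that served as input to the irreproducible discovery rate (IDR) procedure, and 1 list of 8005 regions that passed the authors' IDR threshold. Per the deposited text files, each replicate list was derived from its own alignments and a control file, the pooled list from both alignments and the control file, and the IDR list from the other 3 lists. The peak caller, the aligner, the filters and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' own; its scale is not stated, so it was used to describe and rank regions within a list and as ranks between replicate lists of equal length. The exceptions are the plot of the replicates' values and 1 alternative, Pearson's correlation of log2 signal values between the replicate lists. The deposited −log10 q-values reach 1 top value in each list, which all 8005 IDR regions share, so they were not used for ranking. The other value taken from the files is the authors' summit offset, a position in bp from the start of the region. Read counts were not analysed here, so the depth of each library is unknown and intervals on shares cover counting error of regions only.

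The IDR list was identical to the 8005 strongest regions of the pooled list, so 21995 pooled regions lay outside it, of which 20607 overlapped no IDR region. Comparisons below with pooled regions outside the IDR list used these 20607. Each list held regions on 6 chromosome arms or chromosomes, 2L, 2R, 3L, 3R, X and 4. Gene positions came from the Ensembl annotation and sequence from the NCBI reference assembly, both of the release that dm6 denotes; coordinates are given from 1. Annotated transposable elements were kept out of the gene set.

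A peak was called a promoter peak when its summit lay within 500 bp of any annotated transcription start. Other summits were assigned in the order 5' UTR, coding exon, 3' UTR, noncoding exon, intron and intergenic. Shares were compared with 1000 random placements on the same chromosomes outside assembly gaps by a 2-sided empirical p, of which the smallest possible value is 0.001. Replicates were compared over the 8005 strongest regions of each replicate list with an overlap of at least 1 bp, and by Spearman's rho of signal over the overlapping regions of the whole lists with 100000 permutations. Chromosomes were tested by exact binomial tests against sequence length, and gene lists and gene classes by 2-sided Fisher's exact tests. Promoter and other peaks were compared by a permutation test of the difference in median rank with 100000 resamples, summit positions by an exact binomial test, and head-to-head genes, with starts at most 1000 bp apart, by Fisher's exact test. Motifs were counted in 101 bp windows at the summit and in windows centred 500 bp to each side, and tested by an exact binomial test of windows with the motif at only the summit or only 1 flank. Words of 8 bases were ranked on 1 random part of the IDR list and the leading 200 tested on the 4003 remaining peaks. Confidence intervals are exact binomial intervals at 95%. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05.

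The 27 gene lists, 24 motifs, tests, other settings to try and the rule for named items were fixed before the data were examined. Of the list entries 6 matched no protein-coding gene name of the annotation and were left out, so these lists each lack a gene: phm of ecdysone synthesis, SA of insulator proteins, calypso of Polycomb and trithorax genes, Dl of the Notch pathway, Hop of heat shock and chaperones, and Dat of pigment and tanning. The rule names CG8301, the 20 IDR peaks of highest signal that overlap regions of both replicates, up to 4 members with the strongest promoter peaks of each list that passes, at most 2 of each list that does not, the 3 motifs of lowest adjusted p, and the 5 words of largest held-out ratio. The other settings fixed then were promoter windows of 250 and 1000 bp, the 4002 strongest IDR peaks, the 8005 strongest regions of either replicate alone, other overlap rules, other controls and backgrounds, head-to-head distances of 500 bp and motif windows of 100 bp to each side. Added after the data were seen were random positions matched on the GC of 101 bp, summit windows shuffled with their dinucleotide counts kept, list membership permuted 10000 times within 10 bins of promoter GC, gene lists without the copies of the tandem histone array, and the use of pooled regions in the correlation and base composition.

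The scripts were tested on simulated data. In 40 random sets of 8005 regions the promoter share averaged 0.995 of its expectation, and 4 of the 40 sets gave at least 1 gene list past the threshold, where 2 were expected. Of those 1080 list tests, 2 gave more and 3 gave fewer peaks than other genes. Planted promoter peaks were recovered for 200 of 200 genes and 2 of 2 lists, and a planted motif and a planted word were recovered. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.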

Results

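The authors listed genomic regions, described as peaks and background, for 2 biological replicates of whole fruit fly pupae of 48 h. The pupae carry CG8301 fused to GFP, and each list was derived with a control file. CG8301 is a gene on chromosome arm 3R whose annotated protein of 607 amino acids holds 12 matches to the cysteine and histidine spacing of zinc fingers. The labels give 1 group and no contrast between conditions, so the comparisons are between the replicates, between regions and random positions, and between genes. The description text of both libraries calls them an input control although the antibody field names CG8301, and the regions are described without assigning them to the fused protein. The IDR list, the regions that passed the authors' reproducibility threshold, held 8005 peaks with a median width of 307 bp that covered 2447545 bp. Sequencing depth is unknown.

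At the CG8301 gene itself (FBgn0037717, 3R, 9581306 to 9586648, plus strand, dm6) 1 IDR peak lay at the promoter, from 9581041 to 9581301. Its summit at 9581170 was 136 bp upstream of the annotated start, in the sequence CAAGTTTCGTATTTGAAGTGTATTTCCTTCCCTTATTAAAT. The authors' signal value was 532 and its rank in the IDR list 1945. The replicate lists held this region at rank 2662 in replicate 1 and rank 1668 in replicate 2, with summits 110 and 146 bp upstream of the start. A further region, in an intron 927 bp downstream of the start, ranked 8436 in the pooled list and so lay outside the IDR list; replicate 2 listed it at rank 6509. These are values without a test. Whether the transgene adds reads from further copies of this sequence was not examined.

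The first comparison asked how far the replicates share their regions. Of the 8005 IDR peaks, 6231 (77.8%, exact 95% interval 76.9 to 78.7) overlapped a region among the 8005 strongest of both replicates, against 2.64% ± 0.182 (SD over 1000 sets) for random placements (empirical p = 0.001, the smallest the placements can give). Replicate 1 held 85.2% of the peaks and replicate 2 held 91.6%, and 81 peaks were in neither. Because the IDR list was itself derived from these lists, the share is not independent of them. Over the 7686 peaks with a region in both whole lists, Spearman's rho of the 2 signal values was 0.80 (permutation p = 1e-05, the smallest the resamples can give). This correlation is across peaks, which are not independent replicates.

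**Figure D1:**
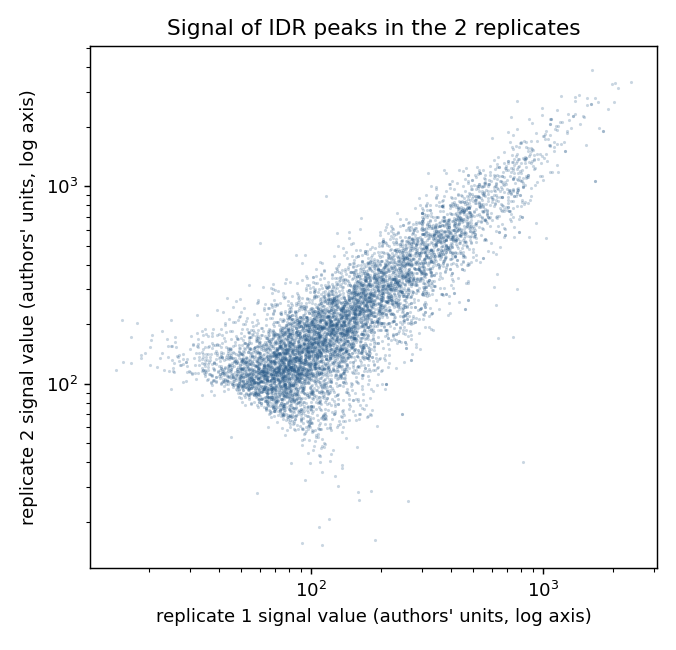
Signal values of the 7686 IDR peaks with a region in both replicate lists, replicate 1 on the x axis and replicate 2 on the y axis, both on log axes in the authors' units; each point is a peak. The 2 values rise together (rho 0.80).

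Of the 20 peaks with the highest signal, 9 were at promoters, 7 in introns, 2 in noncoding exons and 2 between genes. None ranked below 34 in replicate 1 or 43 in replicate 2. The top peak (X, 2703659 to 2704108, signal 5758) had its summit 28 bp upstream of Ugalt, which encodes a UDP-galactose transporter, in the sequence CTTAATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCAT. The next was at the promoter of CG14100 (3L, 19590394 to 19590828, signal 5508), 89 bp upstream of the start. Promoter peaks among the 20 were also found at PNPase, a polynucleotide phosphorylase gene, CG18549, the small heat shock protein gene Hsp27, CenG1A, the chromodomain protein gene Chro, CG31145 and the arginine methyltransferase gene Art3. Intronic peaks had their nearest start at CG11050, the transcription factor gene cbt, Trl, which encodes GAGA factor, Reph, the kinase gene Lk6, CG9663 and CG32772. The peaks in noncoding exons were nearest to the starts of lncRNA:CR44619 and lncRNA:CR46035. The intergenic peaks were nearest to CG31668, 3760 bp from its start, and CG13323, 11980 bp from its start, so the nearest start does not tie these peaks to a gene.

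Promoters held more peaks and coding exons far fewer than random positions did. Summits within 500 bp of a transcription start made up 29.4% of peaks (2356, exact 95% interval 28.4 to 30.4), 2.17 times the 13.6% ± 0.389 (SD) of random placements. Introns held 49.3% against 39.5%, and intergenic sequence 18.6% against 27.2%. Coding exons held 7 peaks, 0.0874% against 13.7%, and 3' UTRs held 0.812% against 4.44%. Each of these 5 differences had an adjusted empirical p of 0.0014, from the smallest p the placements can give. Against random positions of equal GC content, a control chosen after the data were seen, the promoter share was 2.18 times higher (13.5% expected), and the coding exon expectation fell from 13.7% to 3.52%. The 3' UTR expectation rose from 4.44% to 7.74%. The difference for 5' UTRs, 0.612% against 0.773%, did not pass (adjusted permutation p = 0.106), and against 0.563% at positions of equal GC content it was the higher (adjusted p = 0.595). Noncoding exons held 89 peaks, 1.11% against 0.810% at random positions (adjusted permutation p = 0.00583) and 0.789% at positions of equal GC content (adjusted p = 0.00233). The 20607 pooled regions that overlapped no IDR peak lay at promoters in 19.9% of cases, less often than IDR peaks (Fisher's exact p = 3.16e-64). Summits in annotated transposable elements were 18, or 0.225% against 5.75% ± 0.261 (SD) for random positions (permutation of positions, p = 0.001). Random positions were drawn from all sequence outside gaps, while reads from repeated copies cannot be placed uniquely. This deficit is therefore not a measure of avoidance.

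**Figure D2:**
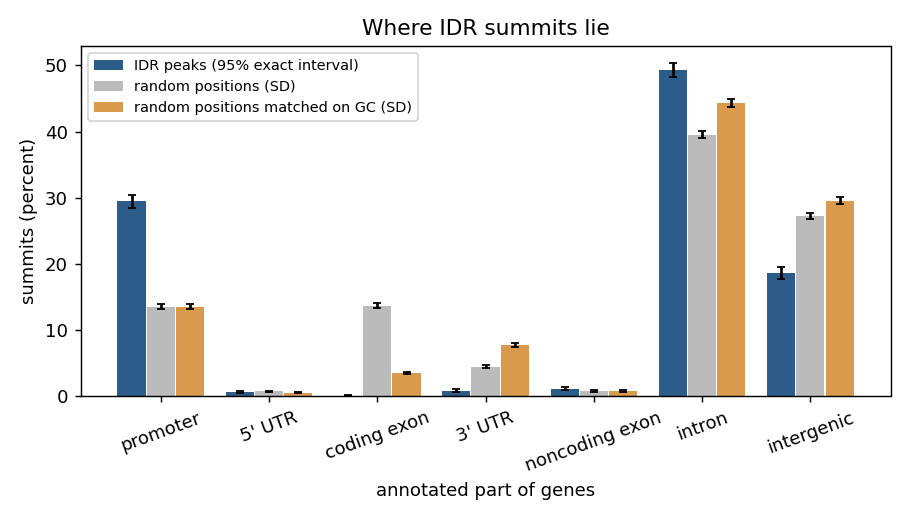
Percent of summits (y axis) in each annotated part of genes (x axis) for the 8005 IDR peaks (exact 95% intervals), random positions (SD of 1000 sets) and random positions of equal GC content (SD of 1000 sets). Promoters hold 29.4% of peaks against 13.6% and 13.5%, and coding exons 0.0874% against 13.7% and 3.52%.

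Promoter summits lay upstream of the start. The median position was -136 bp with quartiles of -240 and 12 bp, and 1738 summits were upstream against 617 downstream (73.8%, exact binomial p = 1.16e-122). The test expects equal numbers on both sides. It does not allow for base composition or for coding exons downstream of starts, so it does not isolate a preference for position. Genes with a promoter peak had a head-to-head neighbour more often than genes without (49.5% of 2257 against 32.0% of 11688, odds ratio 2.08, Fisher's exact p = 1.99e-55). A summit between such neighbours counts for both genes, so the counting rule itself can raise this share. The genes of a pair are not independent in the test, and no random placements were set against it. Promoter peaks had a median rank percentile of 54.1 within the IDR list and other peaks 48.1, a difference of 6.03 points (permutation p = 1e-05). In the 8005 strongest regions of replicate 1 alone it was 0.949 points and did not pass (permutation p = 0.427). Among the 4002 strongest peaks it was 11.8 points (permutation p = 1e-05), and with a window of 250 bp 3.97 points (permutation p = 0.00419).

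Peaks were spread unevenly over the chromosomes, and chromosome 4 had the lowest density. It held 10 peaks, 0.125 times the number expected from its length (adjusted p = 5.84e-22, exact binomial test). The X chromosome held 1549 peaks (1.10 times, exact adjusted p = 5.15e-05) and 3L held 1837 (1.10 times, adjusted p = 2.66e-05). Arm 2R held 1352 (0.893 times, exact adjusted p = 8.53e-06) and 3R held 1818 (0.947 times, adjusted p = 0.0091), while 2L with 1439 (1.02 times, adjusted p = 0.371) did not pass. The X and 3R calls were lost among the 4002 strongest peaks (1.05 and 0.966 times, exact adjusted p = 0.205 and 0.229) and in replicate 2 alone (1.05 and 0.965 times, adjusted p = 0.0569 and 0.0817), where 2L passed with more (1.05 times, exact adjusted p = 0.0385). In replicate 1 alone 2L held 0.988 times its expected number and did not pass (exact adjusted p = 0.639). Against the number of transcription starts 3R did not pass (0.977 times, exact adjusted p = 0.255), and 2L passed with fewer (0.922 times, adjusted p = 0.000691). Chromosome 4 stayed low in that setting (0.161 times, exact adjusted p = 1.06e-15). Expected numbers by length count all sequence outside assembly gaps, including repeated sequence in which reads cannot be placed uniquely. X and autosomes also differ in copy number in pooled males and females, and neither was adjusted for.

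Of 13945 protein-coding genes, 2257 (16.2%) had a promoter peak, and 8 of the 27 gene lists differed from other genes. Genes with more annotated transcription starts have more sequence searched, and these tests did not adjust for the number of starts. The share with a promoter peak also fell with promoter GC, from 22.8% in the lowest of the 10 bins to 6.60% in the highest. With list membership permuted within these bins, a control chosen after the data were seen, the same 8 lists passed. Their adjusted permutation p lay between 0.00135 and 0.0300. In 6 of the lists 1 entry matched no gene name of the annotation and was left out. The 5 lists with more peaks were those of ecdysone response, circadian clock, Notch pathway, EGFR and Ras pathway, and cytoplasmic ribosomal protein genes. The 3 lists with fewer were cuticle proteins, odorant and gustatory receptors, and histones, the last only through the repeated histone array. When only genes with any pooled region in the promoter window were compared, 2 lists passed: cuticle proteins, and the Dpp and Hedgehog pathways, which had fewer (7.14% against 51.4%, exact adjusted p = 0.0193). The 5 lists with more peaks did not pass in that comparison, in which the lists hold fewer genes. The clock list had 85.7% against 51.2% (exact adjusted p = 0.529), ribosomal proteins 61.4% against 51.1% (adjusted p = 0.529), Notch 60% against 51.2% (adjusted p = 0.879), ecdysone response 54.5% against 51.3% (adjusted p = 0.984) and EGFR 50% against 51.3% (adjusted p = 1).

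Ecdysone is the steroid hormone that drives metamorphosis, and 12 of 27 response genes had a promoter peak (44.4% against 16.1%, odds ratio 4.16, exact adjusted p = 0.0027). The strongest were at Eip75B (signal 1288, summit 28 bp downstream of a start), Eip93F (signal 878, 67 bp upstream) and the nuclear receptor genes Hr96 (signal 795) and Hr78 (signal 634). None of 9 ecdysone synthesis genes had one (exact adjusted p = 0.557). Cytoplasmic ribosomal protein genes had a promoter peak in 35 of 92 cases (38.0% against 16.0%, odds ratio 3.21, exact adjusted p = 2.98e-06), led by RpL32 (signal 643), RpS20 (signal 611), RpL7 (signal 369) and RpL24 (signal 348). No excess was seen among the 4002 strongest peaks, with 9.78% against 9.74% (exact adjusted p = 1). Mitochondrial ribosomal protein genes did not pass (15 of 73, exact adjusted p = 0.539), although mRpS23 (signal 4321) and mRpS10 (signal 4054) shared their peaks with CenG1A and Art3.

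Of the Notch pathway genes 9 of 22 had a promoter peak (40.9%, odds ratio 3.60, exact adjusted p = 0.0192), with E(spl)m3-HLH (signal 1266), numb (signal 1091), E(spl)m7-HLH (signal 1054) and neur (signal 902) the strongest. The ligand gene Delta, entered as Dl, was the entry of this list that matched no gene name, so it is not among the 22. The call was lost in replicate 2 alone, where the share was 36.4% against 16.2% (exact adjusted p = 0.0796), and with a window of 250 bp (22.7% against 11.7%, adjusted p = 0.399), while with a window of 1000 bp the share was 59.1% against 20.3% (adjusted p = 0.000352). Of the EGFR and Ras pathway genes 8 of 20 had one (odds ratio 3.46, exact adjusted p = 0.0317), led by the ligand gene spi (signal 2034), aos (signal 561), csw (signal 404) and pnt (signal 289), and with a window of 1000 bp the share was 70% against 20.3% (exact adjusted p = 2.05e-05). Of the circadian clock genes 6 of 11 had one (odds ratio 6.23, exact adjusted p = 0.0177), among them sgg (signal 1809), cry (signal 953), vri (signal 316) and Pdp1 (signal 279). The EGFR call was lost in replicate 2 alone (30% against 16.2%, exact adjusted p = 0.249) and among the 4002 strongest peaks (15% against 9.73%, adjusted p = 0.628). The clock call was lost there too, although the shares were 45.5% against 16.2% (exact adjusted p = 0.0838) and 27.3% against 9.72% (adjusted p = 0.283).

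The list of odorant and gustatory receptors is not limited to these families, since it holds the ionotropic receptor gene Ir67c. Genes of this list had a promoter peak in 2 of 179 cases (odds ratio 0.0577, exact adjusted p = 6.12e-10). Those 2, Or67a and Ir67c, were each outside the 8005 strongest regions of 1 replicate. Among only genes with any pooled region in the promoter window the receptor call was lost (exact adjusted p = 0.296). Cuticle protein genes had 2 of 123 (odds ratio 0.0848, exact adjusted p = 2.63e-06), at Cpr50Ca (signal 195) and Cpr97Eb (signal 149), and with a window of 1000 bp 8.94% against 20.5% (adjusted p = 0.0038). Histone genes had 2 of 118 (odds ratio 0.0885, exact adjusted p = 2.98e-06), at the variant histone genes His3.3B (signal 624) and His2Av (signal 298). In replicate 1 alone the shares were 3.25% of cuticle protein genes (exact adjusted p = 1.76e-05) and 3.39% of histone genes (adjusted p = 2.86e-05), and in either replicate alone 0.559% of the receptor genes had a promoter peak. The histone list holds 111 copies of the tandem array on 2L, from 21416953 to 21541681, in which the pooled list has 0 regions; reads from near-identical copies cannot be placed uniquely, so this count is uncertain. Outside the array 2 of 7 histone genes had a promoter peak (28.6% against 16.3%, exact adjusted p = 0.539), so the call of fewer peaks rests on the array; this comparison was chosen after the data were seen. Members of gene families sit in clusters and are not independent.

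The other 19 lists did not pass. Polycomb and trithorax genes had 9 of 28 (exact adjusted p = 0.105), with strong peaks at ph-p (signal 3282) and brm (signal 1528), and passed in replicate 1 alone (adjusted p = 0.0171) and with a window of 250 bp (adjusted p = 0.0424). Insulator and architectural protein genes had 7 of 21 (exact adjusted p = 0.178), with Chro (signal 4210) and Cp190 (signal 1870). The counts were 8 of 31 for the cell cycle, 5 of 23 for the Wnt pathway, 5 of 24 for heat shock and chaperones, 5 of 28 for muscle structure, 3 of 18 for chitin and molting enzymes and 7 of 44 for translation initiation factors. They were 1 of 8 for Hox genes, 7 of 58 for developmental transcription factors, 3 of 27 for neuronal genes, 8 of 80 for oxidative phosphorylation, 4 of 48 for the proteasome, 1 of 25 for the Dpp and Hedgehog pathways, 1 of 17 for phototransduction, 1 of 15 for pigment and tanning and 0 of 14 for antimicrobial peptides.

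**Figure D3:**
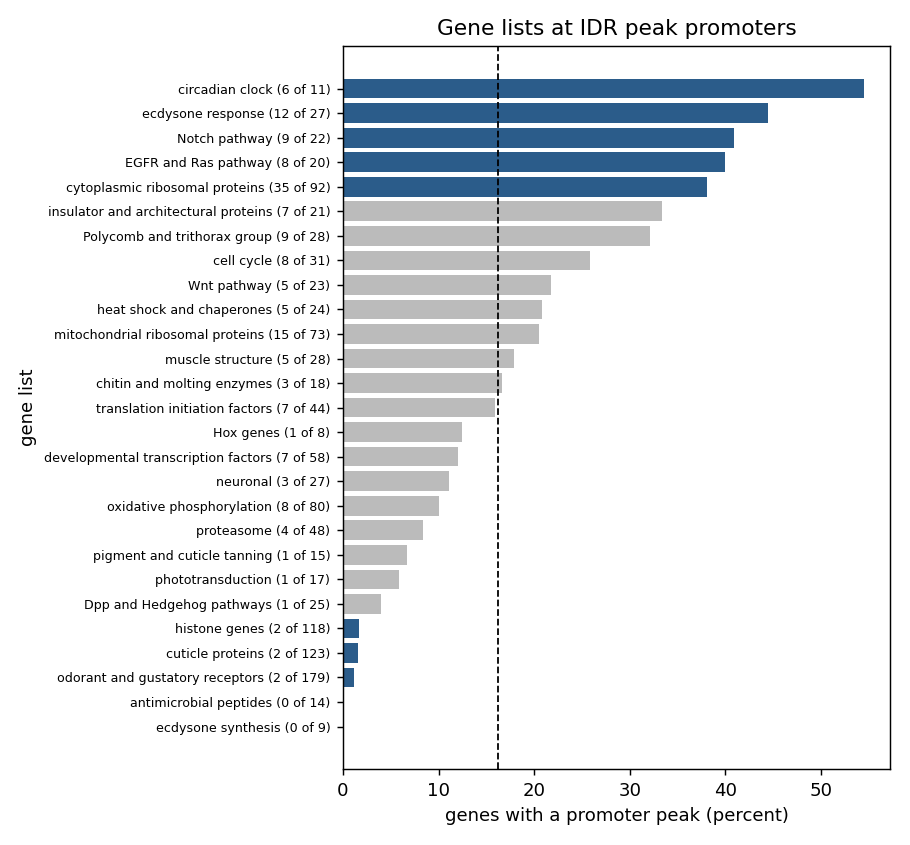
Percent of genes with a promoter peak (x axis) for each of the 27 lists (y axis, with counts); blue bars passed the test at an adjusted p under 0.05 and the dashed line marks the 16.2% of all protein-coding genes. The 5 lists with more peaks range from 38.0% to 54.5%, and the 3 with fewer lie between 1.12% and 1.69%.

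Among other gene classes, 4 of 6 had a promoter peak less often than the 16.2% of protein-coding genes. These were noncoding RNA genes (335 of 3261, 10.3%, exact adjusted p = 7.45e-18), small nucleolar RNA genes (8 of 269, adjusted p = 1.92e-11), pseudogenes (7 of 268, adjusted p = 4.09e-12) and ribosomal RNA genes (0 of 99, adjusted p = 7.07e-08), the last being multicopy genes whose reads cannot be placed uniquely. With a window of 1000 bp small nucleolar RNA genes had 11.9% against 20.4% (exact adjusted p = 0.000592), and among the 4002 strongest peaks 0.743% against 9.74% (adjusted p = 4.34e-09). Transfer RNA genes had 39 of 290 (13.4%, exact adjusted p = 0.227) and small nuclear RNA genes 1 of 32 (adjusted p = 0.0607). Transfer RNA genes passed, with fewer, in replicate 2 alone (9.66%, exact adjusted p = 0.00245) and among the 4002 strongest peaks (5.86%, adjusted p = 0.0319). In replicate 1 alone they had slightly more than protein-coding genes, 17.6% against 17.4% (exact adjusted p = 0.938), as they did with a window of 1000 bp, 21.7% against 20.4% (adjusted p = 0.556). Small nuclear RNA genes passed, with fewer, in replicate 1 alone (exact adjusted p = 0.0392). The tests of gene classes did not adjust for the number of transcription starts of a gene either.

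Summits were centred on an AT-rich stretch. The 101 bp at the summit had a mean GC content of 31.8% ± 8.53 (SD over 8005 peaks) and the flanks 43.3% ± 7.23, a difference of -11.5 points (sign-flip permutation p = 1e-05). The difference was -13.6 points in the 1601 strongest peaks and -8.46 in the 1601 weakest. It was -10.4 points at promoters, -11.3 in introns and -13.6 between genes. In the 8005 strongest regions it was -9.57 points for replicate 1 and -12.0 for replicate 2. In pooled regions outside the IDR list, a comparison chosen after the data were seen, it was -2.55 points (permutation p = 1e-05).

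**Figure D4:**
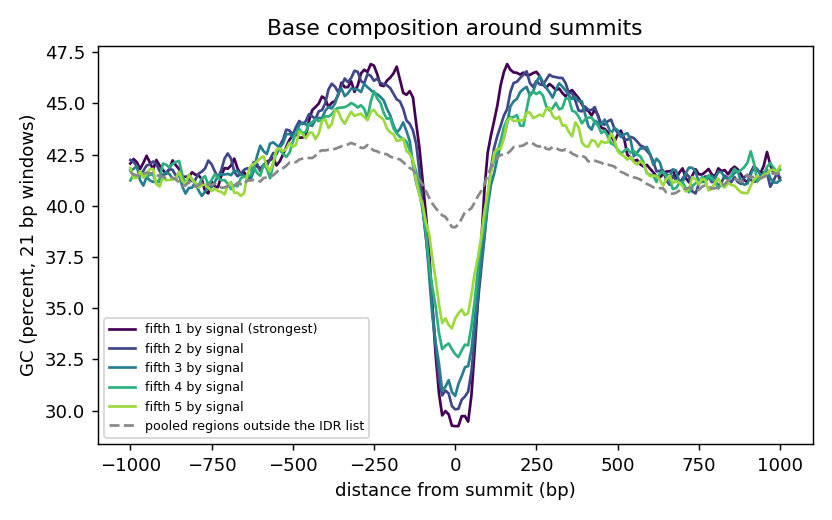
Mean GC content in 21 bp windows (y axis, percent) by distance from the summit (x axis, bp) for 5 equal groups of IDR peaks by signal and for pooled regions outside the IDR list (dashed). The dip is deepest in the strongest group, whose 101 bp at the summit average 29.6% against 34.5% in the weakest.

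Of the 24 motifs, 10 differed between summits and flanks, 5 with more and 5 with fewer at summits, and the 3 with the lowest adjusted p were AT-rich. The TATA box word TATAAA was in 23.8% of summit windows against 10.3% of flanks (2.31 times, adjusted p = 7.07e-107, exact binomial test), the GATA factor site in 24.0% against 15.3% (1.57 times, adjusted p = 1.72e-45), and the homeodomain site TAATTA in 10.6% against 6.30% (1.69 times, adjusted p = 2.83e-23). These 3 excesses were not present against copies of the same windows shuffled with their dinucleotide counts kept, a control chosen after the data were seen. By the exact test the ratios there were 1.01 for the TATA box (adjusted p = 0.677), 0.881 for GATA (adjusted p = 7.2e-06) and 0.766 for the homeodomain site (adjusted p = 7.66e-10), the last 2 being depleted. The motifs with fewer at summits than in flanks were GAGA (0.649 times), the E-boxes CACGTG (0.338) and CAGCTG (0.483), ttk (0.570) and Pho (0.705). Against shuffled windows GAGA (2.80 times, exact adjusted p = 2.04e-10) and CAGCTG (1.85 times, adjusted p = 4.25e-06) had more instead, and CACGTG, ttk and Pho did not pass (adjusted p = 0.0540, 0.263 and 0.347). In that comparison 7 motifs had more and 3 fewer, and for 5 the direction was opposite to that against flanks. Motif 1, a core promoter word, was in 18 windows, 18 times the number in shuffled ones (exact adjusted p = 0.000305), but did not differ from flanks by the test (2.25 times, adjusted p = 0.209). Of 200 words of 8 bases, 146 passed on the 4003 held-out peaks. The largest ratios to flanks were those of ATGTTATA (5.79), ATAACTTA (5.36), ACTATAAT (4.82), AGCATACT (4.60) and AAACTTAT (4.51), with adjusted p from 7.14e-12 to 0.000124. In replicate 1 alone the ratios fell to 3.67 for ATGTTATA, 2.88 for ATAACTTA, 2.29 for AGCATACT and 2.76 for AAACTTAT, and AGCATACT did not pass (exact adjusted p = 0.0784). In replicate 2 alone that of ACTATAAT fell to 3.13. With windows of 100 bp to each side the ratios were 3.22 for ATAACTTA, 2.07 for ACTATAAT and 2.64 for AGCATACT. Against shuffled windows only AAACTTAT of the 5 passed (1.54 times, exact adjusted p = 0.0478), and ATGTTATA (1.02 times, adjusted p = 1), ATAACTTA (1.40 times, adjusted p = 0.173), ACTATAAT (0.976 times, adjusted p = 1) and AGCATACT (2.30 times, adjusted p = 0.0736) did not. Against summits of pooled regions outside the IDR list the 5 ratios lay between 1.46 and 2.25, and AGCATACT did not pass (exact adjusted p = 0.100).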

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

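No paired analysis was possible because the labels give 1 group. The alternatives using GC-matched positions, shuffled windows, GC bins, genes outside the histone array, or pooled regions in the correlation and base composition were chosen after the data were seen. Of 63 alternative values for the main results, 58 kept their direction and side of the threshold or, for counts, stayed within 1.5 times. Of the settings fixed in advance, 2 changed nothing by construction: the 8005 strongest pooled regions are the IDR list, and no list holds other sequences. Leaving out a replicate was not possible for the share and correlation between replicates. The number of gene lists past the threshold, 8, was 5 among the 4002 strongest peaks, 2 against genes with any pooled region in the promoter window, and between 5 and 9 with a replicate left out. The number of chromosomes past the threshold, 5, was 3 among the 4002 strongest peaks. The rank difference of promoter peaks, 6.03 points, was between 0.949 and 8.11 with a replicate left out, 11.8 among the 4002 strongest peaks and 3.97 with a window of 250 bp. The GC difference at summits was -2.55 points in pooled regions outside the IDR list. The cause was not tested, except that the strongest peaks are fewer. Among the named results direction turned in 6 cases where at least 1 of the 2 values passed: for histone genes outside the tandem array (28.6% against 16.3%), for arm 2L against transcription starts (0.922 times), for the EGFR and Ras list against genes with any pooled region (50% against 51.3%), and against 1 shuffled copy of the windows for GATA (0.881), the homeodomain site (0.766) and the word ACTATAAT (0.976). It also turned in 14 cases where neither value passed. These were arm 2L without replicate 2 (0.988 times), transfer RNA genes without replicate 2 (17.6% against 17.4%) and with a window of 1000 bp (21.7% against 20.4%), and 11 cases in 6 gene lists. The lists were those of the Dpp and Hedgehog pathways with a window of 1000 bp (28% against 20.4%), muscle structure with a window of 250 bp, the Wnt pathway and heat shock against genes with any pooled region (41.7% against 51.3% for each), chitin enzymes in 3 settings and translation initiation factors in 4. The share of peaks in both replicates ranged from 71.0% to 97.5% and the promoter share from 19.7% to 40.5% with the window. Unknown depth limits all of these: whether a region absent from a list was too weakly covered cannot be seen.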

Other observations

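Some genes held clusters of peaks. These genes were chosen after their values were seen. Outside promoters, 78 of 13945 protein-coding genes held more IDR summits than their sequence and its GC content give (Poisson test, adjusted p under 0.05). The gene sbb (2R, 18278198 to 18357296) held 26 against 3.63 expected, Snoo (2L, 7891187 to 7984196) held 28 against 4.94, and shn, a zinc finger gene of Dpp signalling (2R, 11159086 to 11217394), held 20 against 2.66. Tet held 22 against 4.33, and the shorter gene drongo (2L, 833584 to 851071) held 9 against 0.494. Mnt held 14 against 1.74 and the nuclear receptor gene Hr4 15 against 2.19. The test treats peaks as independent, and clustered peaks make its p-values too small. Its expected numbers also count coding exons, which held 7 peaks in all, and repeated sequence in which reads cannot be placed uniquely.

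The core of the site of su(Hw), an insulator protein, was singled out after its values were seen. This core shares GCATACT with the named word AGCATACT, so the core and the word are not independent observations. GCATACTT was in 0.974% of summit windows against 0.281% of flanks (3.47 times, exact adjusted p = 2.13e-09), and it remained 2.69 times as frequent as in shuffled windows (exact adjusted p = 1.13e-05). Against summits of pooled regions outside the IDR list the ratio was 1.40 and did not pass (exact adjusted p = 0.0518). In replicate 1 alone the ratio to flanks was 2.28 (exact adjusted p = 0.00115).

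Some regions were strong in both replicates and absent from the pooled list, a count made after the data were seen. Of the 3299 regions among the 4000 strongest of both replicates, 10 overlapped no region of the 30000 in the pooled list, and so could not enter the IDR list. The strongest lay on 3R from 25996447 to 25996827, at the promoter of CG43116, with rank 879 in replicate 1 and 832 in replicate 2. Of the 10, 8 were at promoters: that of CG43116 and those of Sptz, Nadk2, Archease, mgr, CG8132, bark and Nup37.

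The AT-rich core at the summits, whose mean GC stayed under 38.2%, midway between 31.5% at the summit and 45.0% at the shoulders, from -80 to 80 bp, was weighed against technical explanations. The tests were chosen after the GC profile was seen. AT-rich DNA alone does not account for where the peaks lie. The promoter share exceeded that of GC-matched positions by 15.9 points (SD 0.387). That share cannot decide the cause of the core itself, since the GC difference was -10.4 points at promoters and -13.6 between genes. Low GC reaching 250 bp to each side is argued against by the bases 51 to 250 bp from the summits. These were 0.221 points above random positions (SD 0.0829) although they still hold the outer part of the dip. The values cannot decide on the shortest fragments, of 200 bp, most of which the dip can fill. The random positions were also not matched on the annotated part of genes. Libraries enriched for AT-rich fragments stay open. GC over 501 bp was -1.92 points from random positions (SD 0.0827), which met the criterion first set for this explanation, over 2 SD below. The central 101 bp alone move that mean by -2.09 points, so the test does not decide. It was counted as undecided only after this result was seen, and the test of the bases 51 to 250 bp from the summits was added then. Whether words beyond dinucleotide content contribute stays open, because the 200 words chosen on the other peaks departed in both directions. Of these, 17 exceeded shuffled copies of the held-out windows by over 2 SD, against 7.70 (SD 2.36, highest 12) for a shuffled copy set against the rest. A larger number, 27, lay below (5.15 for a copy, highest 10), and the median ratio to the copies was 0.967. Flanks were not tested this way. That 2 of the 5 named words, AGCATACT (1.71 times) and AAACTTAT (1.36 times), exceeded these copies decides nothing, since they were named for their ratios in the same windows. No biological explanation was tested, and the input control label leaves open whether the core belongs to the fused protein or to chromatin in general.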
